A study of Mus musculus with 30 samples.

How the data were processed

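RNA-seq of 30 mouse libraries, labelled as CD45+ tumour-infiltrating immune cells from subcutaneous tumours of 10 lines with 3 replicates each, was analysed from the processed values. Tumours were taken at a length of 10 mm. The labels give RNA as prepared with TRIzol from single cell suspensions of enzymatically digested tumours, and libraries as made with a TruSeq stranded mRNA kit. They mention mice with and without OK-432 in the tumours for 24 hours and both BALB/cJ and C57BL/6J mice, without tying either to libraries. Treatment and host strain were therefore not used as groups. The TPM values were made by the authors: per their processing notes, reads were trimmed with Trim Galore 0.6.5, aligned to mm10 with STAR 2.7.3a and quantified with StringTie 2.1.2. The annotation is not given in the sources used here, and whether strand was used in quantification is not stated. Each library sums to 1000000 TPM over 55291 gene symbols. TPM keep no read counts, so depth per library is unknown and the precision of a single value cannot be given. Reads may be shared within paralog families (Hba and Hbb, Gzm, Klra, Prl2c, Serpinb9), so the levels of single members are uncertain.

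The file was checked for duplicated symbols, unmatched columns and identical libraries, with 0 found of each. Genes at 1 TPM or more in at least 3 libraries were tested, 17944 in all, as log2(TPM + 1). The pseudocount of 1 shrinks fold changes of genes at low levels. A limma model (3.58.1, trend in the variance, R 4.3.3) with a mean for each line and 20 residual degrees of freedom gave an F test over the lines, each line against the mean of the other 9, 3 pairs of related lines (MC38OVA against MC38, CT26NYESO1 against CT26, B16F10 against B16F1), and the difference between the antigen pairs. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison, with a log2 fold change of at least 1 in either direction. SE are those of the fit, and SD are over the 3 libraries of a line. The procedure was tested on simulated data, where it recovered 94% of genes changed by 1.5 (log2) in a line against the others and 88.1% in a pair, with 3 and 4 false calls. The simulation had independent normal noise around 1 mean per gene, and changed only genes above a low level. It held no other line differences and no correlation between genes, so these figures do not give the reliability of calls in the real data.

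Fixed lists of genes, 30 in number with 359 entries of which 335 were tested, covered immune cell types, immune functions, cell states and non-immune tissues, with no gene in more than 1 list. They were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over 300 tests for the lines, and over 90 for the 3 pairs. Counts of members adjusted over the list alone use the same threshold on fold change. List scores were the mean log2(TPM + 1) of the tested members. They were compared over lines by 100000 permutations of the library labels, and for each line by all 4060 exact splits of 3 from 30 libraries, where 0.00025 is the smallest possible p. Correlations of 6 list scores over line means used permutation p values with n = 10. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Coordinates are from GENCODE M21 on mm10.

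Comparisons, lists, thresholds, most alternatives and the rule for named genes were set before the data were examined. For each line the rule took the 8 rises and 5 falls with the largest change among called list members, and the 5 rises and 3 falls with the largest change among all called genes, leaving out predicted genes and receptor segments. For each pair it took 10 rises and 10 falls among all genes and 5 of each among list members, and for the difference between pairs 5 of each. It picked 10 to 25 genes per comparison, and each is named except 3, in 3 comparisons, that are not reported here. For each list described, examples come from its 4 members with the largest change. The leukocyte score of 10 genes, its subtraction from list scores, its use as a covariate and the exclusion of B16F1 and B16F10 from the compared lines were chosen after seeing the data. The alternatives were median-ratio scaling, a pseudocount of 0.1, no filter, no fold threshold, leaving out each library or replicate number, related lines averaged into 7 families, leaving out the related line, a fit of only the 6 libraries of a pair, list scores from z-scores of genes, and replicate number as a block. Nothing in the labels says that replicates came from separate mice, so p values of the limma fit measure the spread between these samples. Permutation p values over libraries treat the libraries as exchangeable and do not measure that spread.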

Results

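The data were 30 mouse RNA-seq libraries, 3 for each of 10 subcutaneous tumour lines, labelled as CD45+ tumour-infiltrating immune cells. The lines were MC38 (colon carcinoma), MC38OVA (MC38 carrying ovalbumin), EMT6 (mammary carcinoma), LL2 (Lewis lung carcinoma), CT26 (colon carcinoma), CT26NYESO1 (CT26 carrying the human antigen NY-ESO-1), CMS5a (fibrosarcoma), Renca (renal carcinoma), and B16F1 and B16F10 (sublines of a melanoma). The stated purpose was to find tumour types suited to OK-432, a killed streptococcal preparation given into tumours. The labels do not say which libraries, if any, came from treated mice. TPM values keep no sequencing depth, so the depth of each library is unknown and no counting interval can be given. Each library had between 12065 (B16F10 replicate 2) and 14602 (MC38OVA replicate 3) genes at or above 1 TPM. Mitochondrial transcripts took 9.17% (EMT6 replicate 1) to 39.0% (B16F1 replicate 2) of TPM, and haemoglobin transcripts 0.0222% (B16F1 replicate 1) to 7.70% (B16F10 replicate 2). Replicates of a line correlated at r = 0.950 or above across genes, which are not independent replicates, with the lowest value in B16F1. Xist, the transcript that silences the X chromosome of female cells, was highest in LL2 at 66.9 ± 4.75 TPM (SD, n = 3), while the Y-linked Ddx3y, Eif2s3y and Uty were listed at 0 in every library and Kdm5d reached at most 0.0346 TPM.

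The main question was how the libraries of the 10 lines differ. Among members of the fixed lists, those with the widest range of line means were mostly markers of the tumours' own tissues, and genes outside the lists were not ranked here. Tyrp1, Dct and Pmel, which act in melanin synthesis and melanosomes, reached 3750 ± 660, 3608 ± 934 and 2833 ± 667 TPM in B16F10 (SD, n = 3), against at most 1.01 TPM of Pmel in any line other than B16F1 and B16F10. Krt8 and Krt18, keratins of simple epithelia, reached 926 ± 219 and 576 ± 176 TPM in Renca and lay below 1 TPM in B16F10. Col3a1, a fibrillar collagen, was highest in CMS5a at 2566 ± 397 TPM and lowest in B16F10 at 3.10 TPM. Gzmc, a granzyme of activated killer lymphocytes, was the only immune gene among these 10, from 0.486 TPM in Renca to 676 ± 134 TPM in MC38. Mlana, Trpm1 and Slc45a2, also melanocyte genes, completed these 10 list members, with 724 ± 114, 448 ± 88.9 and 419 ± 71.4 TPM in B16F10. In the limma fit over all lines, 15338 of 17944 genes (85.5%) differed at an adjusted p under 0.05 with group means at least 1 apart (log2). The adjusted p of these 10 genes lay between 4.1e-14 for Gzmc and 7.6e-26 for Tyrp1. Tyrp1 lies on chromosome 4 at 80834123 to 80851719, Pmel on chromosome 10 at 128704195 to 128720238 and Gzmc on chromosome 14 at 56231441 to 56234656 (mm10).

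**Figure D1:**
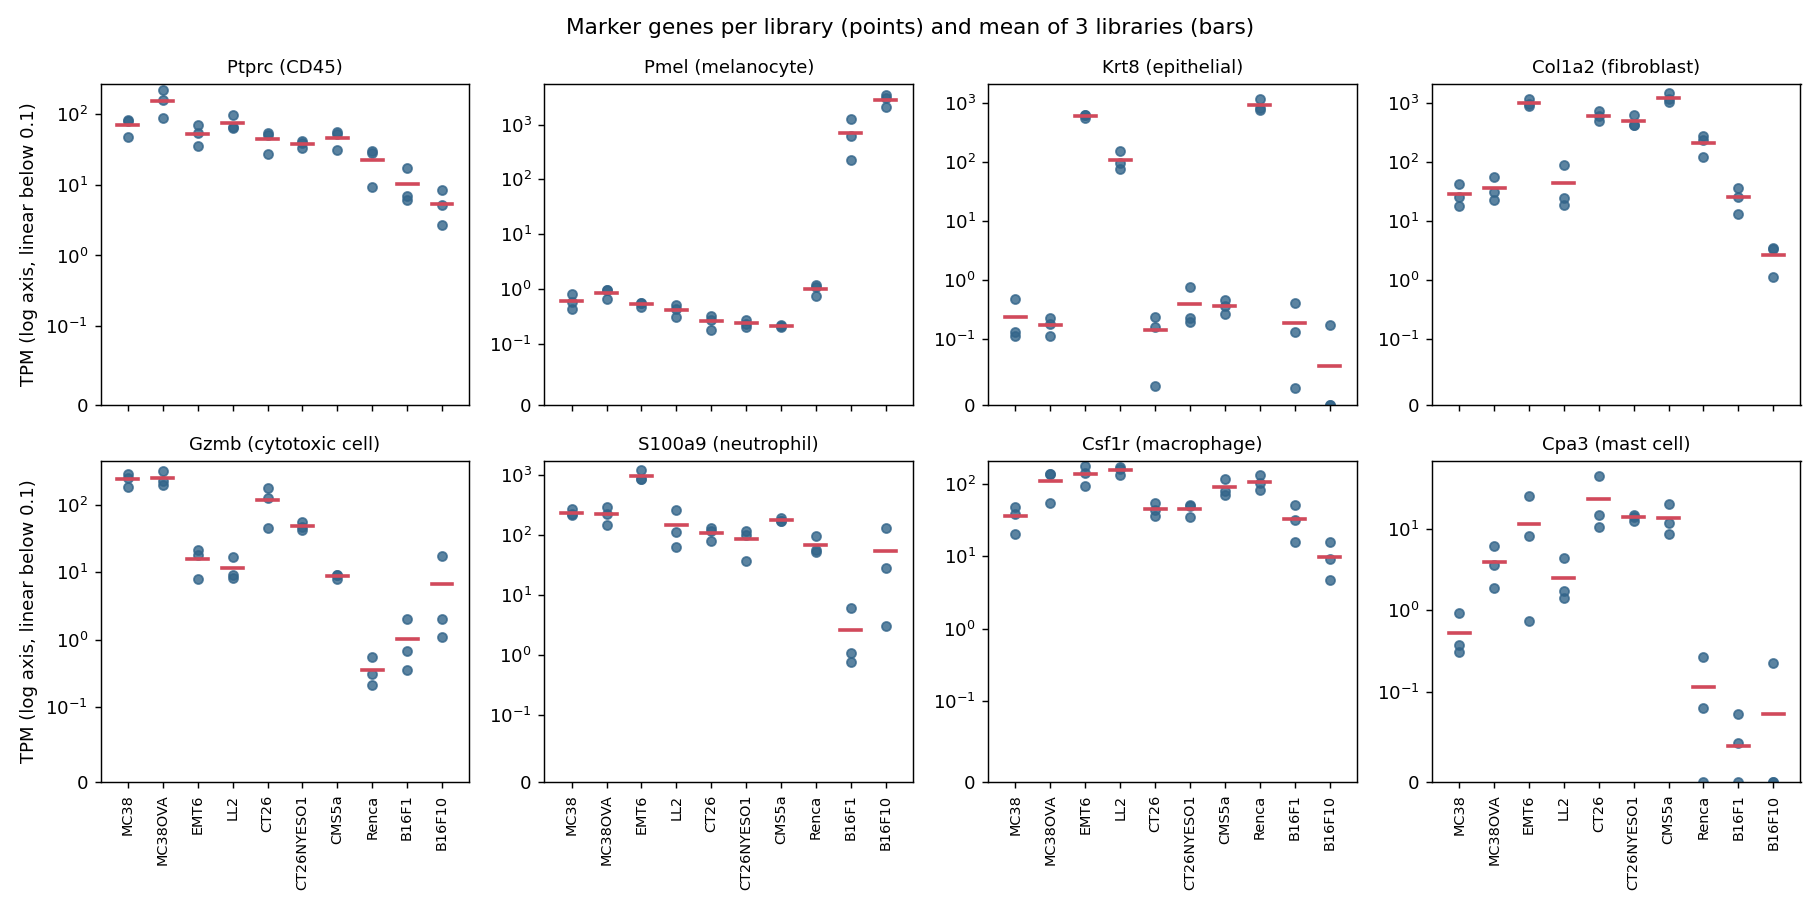
Levels of 8 marker genes in TPM (log axis, linear below 0.1) for the 3 libraries of each of the 10 lines, with points for libraries and bars for means. Pmel stands at 698 TPM in B16F1 (425 without B16F1 replicate 1) and 2833 TPM in B16F10, and Ptprc averages 154 TPM in MC38OVA and 5.39 TPM in B16F10.

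Leukocyte transcripts varied widely between lines. Ptprc, the gene for CD45 (chromosome 1, 138062861 to 138175708), averaged 154 ± 64.0 TPM in MC38OVA, 22.4 ± 11.4 in Renca, 10.1 ± 6.26 in B16F1 and 5.39 ± 2.83 in B16F10 (SD, n = 3). A score over 10 genes expressed by most leukocytes (Ptprc, Cd53, Laptm5, Coro1a, Lcp1, Was, Ikzf1, Arhgdib, Cd52 and Fermt3), chosen after seeing the data, was higher in MC38OVA than in the other 27 libraries by 1.56 (log2, exact permutation p = 0.0091). The difference was -1.63 in B16F1 (exact permutation p = 0.0062) and -1.82 in B16F10 (exact permutation p = 0.002). The other 7 lines lay between -0.44 for Renca and 1.04 for LL2, with exact permutation p of 0.083 or more. These p values are two-sided and were not adjusted over the 10 lines.

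The immune lists were scored as the mean of log2(TPM + 1) over their members, and 29 of the 30 lists differed between lines by permutation. The muscle and adipocyte list did not (permutation p = 0.13). MC38OVA had the highest scores for monocytes, conventional dendritic cells, NK cells, T cells, CD8 T cells with cytotoxicity, T cell exhaustion, regulatory T cells, pattern recognition, interferon response and MHC class I presentation. EMT6 led in neutrophils, myeloid suppressive mediators, chemokines, hypoxia with glycolysis, and dissociation stress. Renca led in mature dendritic cells, eosinophils, MHC class II presentation and epithelial genes. CMS5a led in plasmacytoid dendritic cells, B cells, plasma cells, fibroblasts and endothelium, LL2 in macrophages, CT26 in mast cells with basophils, and MC38 in proliferation. B16F10 led in melanocyte and erythroid genes. For each line, the 3 libraries were set against the other 27 by exact permutation, two-sided and adjusted over 300 tests. These p values treat the 30 libraries as exchangeable, although they come in 10 lines. A low p therefore shows that the mean of the 3 libraries is extreme among such splits, not that each library is. The line itself is a single unit. The CD8 T cell and cytotoxicity score was higher in MC38 by 2.27 (adjusted p = 0.034) and in MC38OVA by 2.51 (adjusted p = 0.015), both by exact permutation. The neutrophil score was higher in EMT6 by 2.11 (exact permutation, adjusted p = 0.033), the mast cell score in CT26 by 1.68 (0.035), the B cell score in CMS5a by 1.16 (0.0062) and the eosinophil score in Renca by 1.66 (0.0062). CT26 replicates 1, 2 and 3 had mast cell scores of 3.917, 2.579 and 2.980, while EMT6 replicate 2 stood at 3.456. MHC class I presentation changed by -3.02 in B16F1 (exact permutation, adjusted p = 0.0062), and by -1.39 relative to the leukocyte score, which did not pass (exact permutation, adjusted p = 0.054). The eosinophil score rests on few genes, since 2 of its 7 members passed the filter. The 17 lists of immune cell types, suppressive mediators, checkpoints and pattern recognition, which leave out MHC and interferon, gave 170 combinations with the 10 lines. Of these, 26 passed as scored and 19 once the leukocyte score of each library was subtracted, with 5 in both and in the same direction. The 5, relative to leukocytes, were CD8 T cells and cytotoxicity in MC38 at 1.89 (exact permutation, adjusted p = 0.013), neutrophils in EMT6 at 1.45 (0.034), mast cells in CT26 at 1.71 (0.02), eosinophils in Renca at 2.09 (0.012), and monocytes in MC38OVA at 0.81 (0.047). The 14 that passed only after subtraction lay in 6 lines. B16F1 had a higher macrophage score at 1.14 (exact permutation, adjusted p = 0.013; -0.49 before subtraction). Its conventional dendritic cell score was higher at 1.44 (exact permutation, adjusted p = 0.026; -0.195 before) and its regulatory T cell score at 1.09 (0.034; -0.540 before). All 3 were lower before subtraction, so these rises come from the low leukocyte score of B16F1, at 4.245. The macrophage list also holds Gpnmb, a gene of melanosomes too. MC38 had higher NK cells at 1.49 (exact permutation, adjusted p = 0.029). LL2 had lower T cells at -1.51 (exact permutation, adjusted p = 0.031), exhaustion genes at -1.22 (0.012), plasmacytoid dendritic cells at -1.39 (0.012), B cells at -1.39 (0.034) and plasma cells at -1.34 (0.041). Before subtraction these LL2 scores lay between -0.468 for T cells and -0.182 for exhaustion genes, and none passed. Much of each fall therefore comes from the leukocyte score of LL2, which was higher by 1.04. EMT6 had lower NK cells at -1.42 (exact permutation, adjusted p = 0.042; -0.758 before subtraction) and T cells at -1.33 (0.046; -0.670 before). MC38OVA had lower plasma cells at -1.30 (exact permutation, adjusted p = 0.046), though their score was higher before subtraction (0.259). Renca had lower monocytes at -0.88 (exact permutation, adjusted p = 0.02) and higher mature dendritic cells at 1.15 (0.034). With a pseudocount of 0.1, 4 of these 14 were lost: T cells and B cells in LL2 (exact permutation, adjusted p = 0.063 and 0.061), NK cells in EMT6 (0.077) and plasma cells in MC38OVA (0.11).

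**Figure D2:**
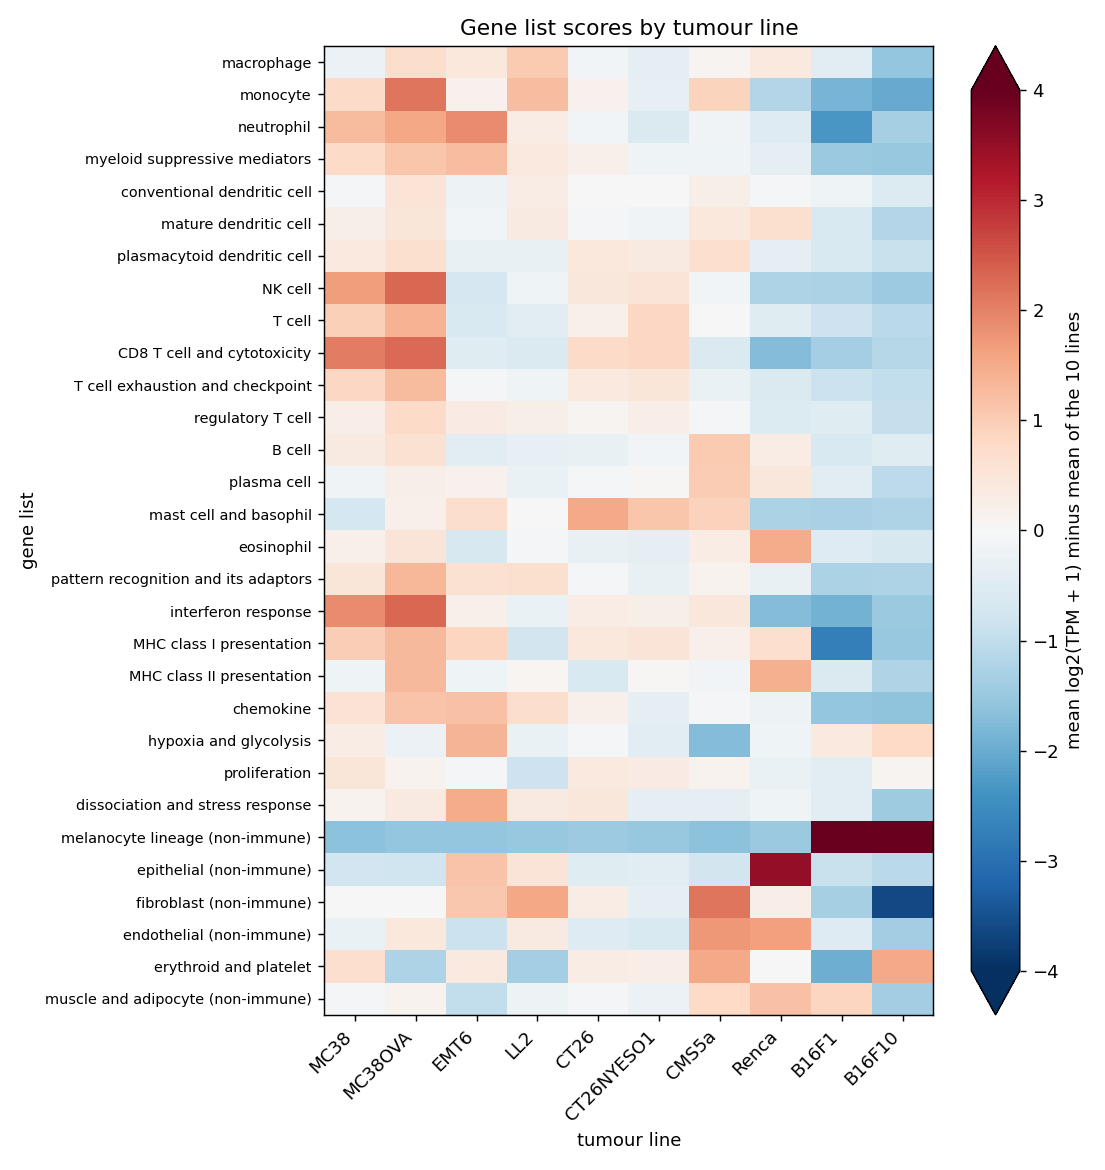
Mean score of each of 30 gene lists (vertical) in each of 10 tumour lines (horizontal), as the difference in log2(TPM + 1) from the mean of the 10 lines, shown by colour with the scale ending at 4 and -4. The interferon response list is highest in MC38OVA at a score of 7.47 and lowest in B16F1 at 3.29, n = 3 libraries per line.

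Each line was then compared with the mean of the other 9 lines to ask what sets its libraries apart. Fold changes compare means of log values, so arithmetic means can lie the other way. In LL2, Krt8 had a log2 fold change of 4.38 at a mean of 109 TPM, while the other line means ran from 0.0595 to 926 TPM and averaged 171 TPM. A scaling of the libraries by median ratios shifted the log2 fold changes of single genes. The median shift over genes was -0.14 in MC38, EMT6 and CMS5a, -0.11 in CT26NYESO1, 0.15 in B16F1 and 0.50 in B16F10. None of the named genes or lists changed direction under this scaling. The higher share of called genes moved by more than 10 points in B16F10 alone among the lines. Of the camera list tests, 89 of 300 passed with the preset correlation and 1, epithelial genes in Renca, held with an estimated correlation. The falls of Dct in MC38, MC38OVA, EMT6, LL2, CT26 and CT26NYESO1 (log2 fold changes between -2.48 and -2.59), and those of Pmel and Tyrp1 in EMT6 and CT26, were measured against a mean that holds B16F1 and B16F10. With both left out, an alternative chosen after seeing the data, these values lay between -0.28 for Pmel in CT26 and 0.07 for Dct in CT26NYESO1. The melanocyte list of the 8 other lines is therefore not described by line. Krt8 likewise reached at most 0.773 TPM in any library outside EMT6, LL2 and Renca. Its falls in MC38, MC38OVA, CT26 and CT26NYESO1, given below, were measured against a mean that holds those lines.

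**Figure D3:**
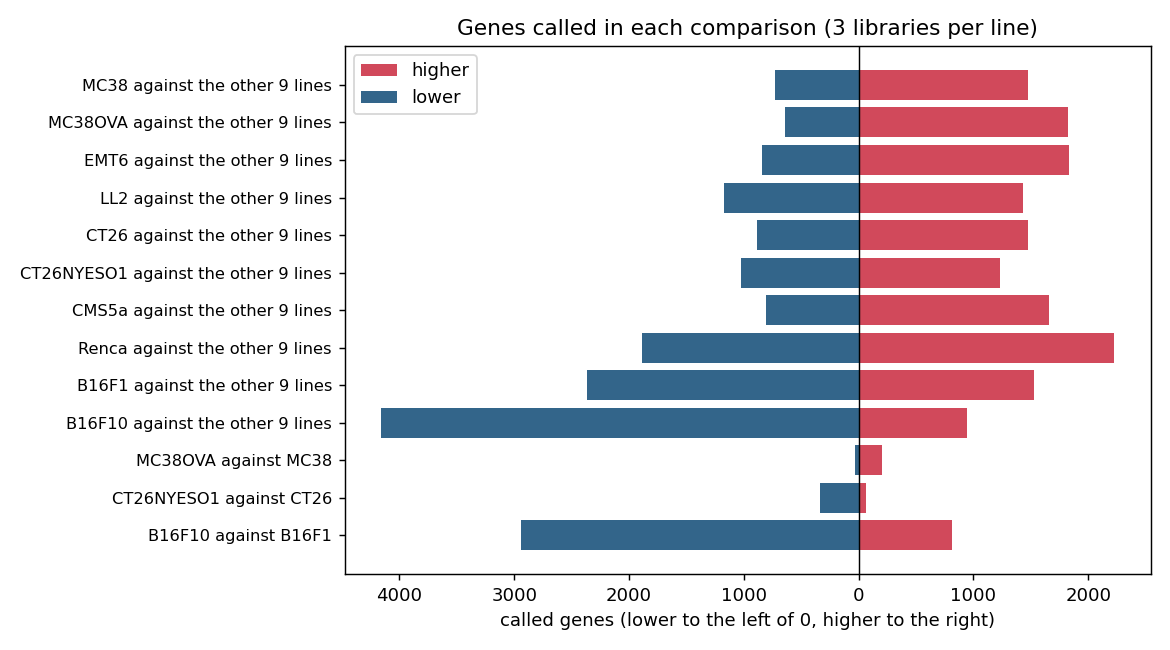
Number of genes called higher (right of 0) and lower (left of 0) in each line against the other 9 lines and in the 3 pairs of related lines, n = 3 libraries per line. Bars run from 4158 genes lower in B16F10 to 30 genes lower in MC38OVA against MC38.

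MC38 and MC38OVA libraries were rich in transcripts of killer lymphocytes and of the interferon response. Gzmc stood at 676 ± 134 TPM in MC38 and 457 ± 57.4 in MC38OVA (SD, n = 3), with log2 fold changes of 5.70 ± 0.43 and 5.09 ± 0.43 (SE) against the other lines. Gzmb, another granzyme, reached 246 ± 55.1 and 251 ± 61.5 TPM, and the pore-forming Prf1 89.0 ± 11.4 TPM in MC38. The interferon-induced chemokine Cxcl10 averaged 855 ± 142 and 942 ± 51.4 TPM, and the antiviral Rsad2 289 ± 26.5 TPM in MC38. All 18 interferon response genes were higher in MC38 and in MC38OVA (18 in each adjusted over the list alone), and the camera calls were lost at an adjusted p = 0.66 and 0.6 with an estimated correlation. Of 12 CD8 T cell and cytotoxicity genes, 11 were higher in each line (11 in each adjusted over the list alone; adjusted p = 0.69 in MC38 and 0.64 in MC38OVA with an estimated correlation). The NK cell list had 9 and 10 of 10 genes higher, the same counts adjusted over the list alone, with an adjusted p = 0.65 and 0.6 under an estimated correlation. By exact permutation the NK cell and interferon scores passed in MC38OVA (2.55, adjusted p = 0.012; 2.54, adjusted p = 0.0092) but not in MC38 (adjusted p = 0.069 and 0.06). Relative to the leukocyte score this turned round. NK cells and interferon passed in MC38 (1.49, exact permutation adjusted p = 0.029; 1.72, adjusted p = 0.013) but not in MC38OVA (0.98, adjusted p = 0.21; 0.97, adjusted p = 0.26). In MC38OVA the CD8 T cell and pattern recognition scores also did not pass relative to leukocytes (exact permutation, adjusted p = 0.37 and 0.82). Klra4, a receptor of natural killer cells, led the NK cell list at log2 fold changes of 4.31 ± 0.11 and 4.26 ± 0.11. The lines differ in strain of origin, and strain differences in NK receptor genes were not separated from NK cell content in any line. Ido1, a tryptophan-degrading enzyme that restrains T cells, and the monocyte attractant Ccl2 were higher in MC38 by 3.48 ± 0.26 and 3.03 ± 0.27. MC38OVA also had monocyte genes, with 7 of 9 higher (7 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation). Ly6c2, a surface marker of inflammatory monocytes, averaged 675 ± 355 TPM, and Chil3 and Ms4a4c rose by 4.29 ± 0.41 and 3.79 ± 0.34. In the same line, 14 of 20 pattern recognition genes were higher (14 adjusted over the list alone; adjusted p = 0.65 with an estimated correlation), led by Tlr9, a sensor of unmethylated DNA, at 3.73 ± 0.31.

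Over all genes, Shisal2b (chromosome 13, 104845283 to 104863893) had the largest rise of both lines, 8.13 ± 0.11 and 7.67 ± 0.11, followed by Prl2c2 at 6.91 and 6.53, Fmr1nb at 5.78 and 5.51, and Prl2c3 at 5.57 and 5.38. Prl2c genes are paralogs of the prolactin family, and reads may be shared among them. H2-Ea was listed at 0 in both lines, against other line means from 0 to 444 TPM. Atp6v0e2 fell in both lines (-3.78 and -3.76), Cryab and Cadm1 in MC38 (-3.80 and -2.40), and Gchfr, Adm and Hbb-bs in MC38OVA (-3.62, -2.19 and -2.20). Col1a2 was lower in MC38 at -2.15 ± 0.33. Krt8 and Krt18 were lower in both, between -2.75 and -3.07. In all, 1479 genes were higher and 728 lower in MC38, and 1827 and 644 in MC38OVA. The leukocyte score was higher in MC38OVA by 1.56 and lay at 0.38 in MC38.

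EMT6 libraries held neutrophil genes at high levels, as well as hypoxia and stress genes as scored, and the single genes Krt8 and Acta2. Krt8 (chromosome 15, 101996698 to 102004482) averaged 610 ± 36.9 TPM (SD, n = 3), a log2 fold change of 7.20 ± 0.16 (SE), and Acta2, the actin of smooth muscle and myofibroblasts, 347 ± 66.5 TPM (5.50 ± 0.21). S100a9, a subunit of the neutrophil protein calprotectin, reached 976 ± 195 TPM against an average of 122 TPM over the other lines. Of 13 neutrophil genes 10 were higher (10 adjusted over the list alone; adjusted p = 0.68 with an estimated correlation), among them Stfa2l1 at 3.32 ± 0.39 and G0s2 at 3.26 ± 0.34. Ptgs2 (cyclooxygenase-2, the inducible enzyme of prostaglandin synthesis) rose by 4.88 ± 0.28 and led the myeloid suppressive list, of which 8 of 18 genes were higher (8 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation). The hypoxia and glycolysis list had 9 of 15 genes higher (9 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation), with Adm, a vasodilator peptide induced by low oxygen, at 245 ± 40.6 TPM. Of 12 dissociation and stress genes 11 were also higher (11 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), with the heat shock gene Hspa1b at 3.49 ± 0.40. By exact permutation the hypoxia (1.52, adjusted p = 0.025) and stress scores (1.65, 0.0062) passed, and the suppressive score did not (1.36, 0.06). Relative to leukocytes none of these 3 passed: 0.86 (exact permutation, adjusted p = 0.58), 0.99 (0.15) and 0.70 (0.055; 0.024 with a pseudocount of 0.1). Cxcl5 and Cxcl2, attractants of neutrophils, rose by 4.69 ± 0.24 and 3.52 ± 0.42, and Col1a2 by 3.57 ± 0.33. Dynap, Crabp2 and Serinc2 also rose, by 7.06, 6.81 and 6.32. Rhox5 (-7.01 ± 0.20), Ppic (-5.56), Tfpi (-5.08), Gpnmb (-4.37) and Lum (-2.14) were lower. The counts were 1831 genes higher and 843 lower, at a leukocyte score difference of 0.66 and mitochondrial transcripts of 10.5%, the lowest mean of the lines.

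LL2 libraries carried many, but not all, of the listed genes of matrix-producing fibroblasts together with macrophage genes. Lum, a collagen-binding proteoglycan (chromosome 10, 97565128 to 97572703), averaged 496 ± 81.3 TPM (SD, n = 3), a log2 fold change of 5.98 ± 0.34 (SE). Fbn1, Col3a1 and Dcn, also of the extracellular matrix, rose by 4.07 ± 0.25, 4.06 ± 0.32 and 3.66 ± 0.31, and Mmp3, a matrix-degrading protease, by 6.79 ± 0.35. Of 12 fibroblast genes, 7 were higher and 2 lower (9 called when adjusted over the list alone; adjusted p = 0.72 with an estimated correlation). Col1a2 did not rise with the others, at 24.3, 87.2 and 18.9 TPM in the LL2 libraries, against 866 to 1170 TPM in those of EMT6. The macrophage list had 13 of 18 genes higher and 1, Gpnmb, lower at -2.77 (14 called when adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). By exact permutation neither list passed: macrophages 1.16 (adjusted p = 0.071), 0.12 relative to leukocytes (adjusted p = 0.9), and fibroblasts 1.72 (adjusted p = 0.21). Arg1, the arginine-degrading arginase of suppressive myeloid cells, averaged 398 ± 185 TPM, and Mertk, Folr2 and Cd163 rose by 2.31 ± 0.17, 2.02 ± 0.34 and 1.91 ± 0.23. Vcan, a proteoglycan of monocytes and stroma, rose by 4.54 ± 0.28. The proliferation list had 5 of 14 genes lower and 0 higher (5 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation), including Rrm2 at -1.35 ± 0.19 and Cdc20 at -1.34 ± 0.18. By exact permutation that score passed (-0.90, adjusted p = 0.027), and relative to leukocytes (-1.94, adjusted p = 0.043; 0.051 with a pseudocount of 0.1). Krt18 and Krt8 rose by 4.40 and 4.38. Nptx1, Dkk2 and H19, an imprinted RNA of fetal tissue, had rises of 6.65, 6.51 and 6.24. Tinagl1 (-4.34), Sardh (-3.80), Car9 (-2.79), Hbb-bs (-2.56) and Hbb-bt (-2.46) fell, and H2-Ea was listed at 0. The counts were 1432 genes higher and 1172 lower, with a leukocyte score difference of 1.04. The larger side turned with B16F1 and B16F10 left out (1147 higher, 1405 lower), a pseudocount of 0.1 (2335 and 2347) and no fold threshold (3959 and 4856).

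CT26 libraries held mast cell proteases at high levels. The mast cell genes Tpsb2, Cma1 and Cpa3 averaged 44.0 ± 32.2, 31.5 ± 27.9 and 23.6 ± 18.8 TPM in CT26 (SD, n = 3), with log2 fold changes of 3.05 ± 0.45, 2.71 ± 0.44 and 2.64 ± 0.43 (SE). Without CT26 replicate 1 the means were 26.1, 15.6 and 12.8 TPM and the fold changes 2.50, 2.05 and 2.05, with the calls kept. In CT26NYESO1 the same genes rose by 2.17 ± 0.45, 2.16 ± 0.44 and 2.13 ± 0.43, and the mast cell transcription factor Gata2 by 1.90 ± 0.17. Of 9 mast cell and basophil genes, 6 were higher in CT26 and 5 in CT26NYESO1 (6 and 5 adjusted over the list alone), with an adjusted p = 0.75 and 0.84 under an estimated correlation. By exact permutation the list did not pass in CT26NYESO1 (1.22, adjusted p = 0.24; 1.26 relative to leukocytes, adjusted p = 0.14). Its score of 2.75 there lay close to 2.57 in CMS5a and 2.36 in EMT6. Gzma, a granzyme of killer cells, averaged 102 ± 63.5 TPM in CT26 and 49.4 ± 15.9 in CT26NYESO1, and Gzmb 118 ± 66.4 in CT26. Egr1, an immediate early transcription factor, rose by 2.94 ± 0.15 in CT26. Tigit, a checkpoint receptor of T cells, rose by 1.88 ± 0.27 in CT26NYESO1, and Ptges, the prostaglandin E synthase, by 2.17 ± 0.17. Col1a2 was higher in both, at 2.75 and 2.40, and Dcn in CT26 at 2.50. Baiap2l1 led all genes of CT26 at 6.71 ± 0.20 and reached 6.41 ± 0.20 in CT26NYESO1, with Esm1 at 6.39 and 5.81 and Amigo2 at 6.16 and 6.11. Krt20, a keratin of intestinal epithelium (chromosome 11, 99428403 to 99438150), and Rarres1 rose in CT26 by 6.54 and 6.32, and Cldn6, a tight junction protein, and Rpl39l in CT26NYESO1 by 6.41 and 5.75. Ldhb, the heart-type lactate dehydrogenase, fell in both (-3.60 and -3.69), as did Krt8 (-2.88 and -2.57) and Egln3 (-1.96 and -2.65). Sgce fell in CT26 (-3.48), where Wfdc2 was listed at 0, and Gpnmb, Enpp2 and Cxcl3 fell in CT26NYESO1 (-3.92, -3.81 and -2.53). The counts were 1480 genes higher and 881 lower in CT26, and 1228 and 1024 in CT26NYESO1. In CT26NYESO1 the larger side turned with median-ratio scaling (1020 higher, 1133 lower), a pseudocount of 0.1 (2033 and 2206) and B16F1 and B16F10 left out (894 and 1177). The leukocyte score differences were -0.03 and -0.04.

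CMS5a libraries showed endothelial and B cell genes at high levels and hypoxia genes at low levels as scored, and many single fibroblast genes at high levels. Fabp4, a fatty acid carrier of adipocytes, macrophages and capillary endothelium (chromosome 3, 10204088 to 10208576), averaged 1543 ± 258 TPM (SD, n = 3), against at most 24.7 TPM in any other line, a log2 fold change of 6.83 ± 0.30 (SE). Of 12 fibroblast genes 10 were higher (10 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), led by Col3a1 at 4.22 ± 0.32, Col1a2 at 3.87 ± 0.33 and the growth factor receptor Pdgfra at 3.60 ± 0.20. Lum, Dcn and Vcan rose by 3.30, 3.10 and 3.64. The endothelial list had 8 of 10 genes higher (8 adjusted over the list alone; adjusted p = 0.36 with an estimated correlation), with Emcn at 3.06 ± 0.25 and the cadherin Cdh5 at 3.03 ± 0.23. B cell genes were higher in 4 of 7 cases (4 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), including the receptor subunit Cd79a at 2.12 ± 0.18. Among 7 plasma cell genes 5 were higher (5 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), with Ighm at 64.5 ± 3.76 TPM. The hypoxia and glycolysis list had 14 of 15 genes lower (14 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), among them Bnip3, a mitochondrial protein induced by low oxygen, at -3.06 ± 0.27 and Ankrd37 at -2.91 ± 0.30. By exact permutation the endothelial (1.92, adjusted p = 0.018), B cell (1.16, 0.0062), plasma cell (1.14, 0.0092) and hypoxia scores (-1.91, 0.0062) passed, and the fibroblast score did not (2.38, 0.084). Relative to leukocytes the fibroblast score passed (2.06, exact permutation adjusted p = 0.034; 0.051 with a pseudocount of 0.1). The endothelial (0.093), B cell (0.31), plasma cell (0.3) and hypoxia scores (0.077) then did not pass, except B cells with a pseudocount of 0.1 (0.024). Efemp1, Rpl39l, Col5a2 and Cox7b2 had the largest rises after Fabp4, between 5.70 and 6.09. Kctd15 (-4.01), Clu (-3.89), the metallothionein Mt2 (-3.84), Gzmc (-3.26), Hspa1b (-3.09), Cxcl2 (-3.02) and Krt18 (-2.94) were lower. The counts were 1657 genes higher and 805 lower, with a leukocyte score difference of 0.32 and haemoglobin transcripts of 3.16%.

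Renca libraries had the highest epithelial score of the lines, with the kidney genes Cdh16 and Fxyd2 at high levels and the granzymes Gzmb and Gzmc at low levels. Cdh16, a cadherin of kidney tubules (chromosome 8, 104601911 to 104624396), averaged 366 ± 1.16 TPM (SD, n = 3), against at most 0.0593 TPM in any other line, and Fxyd2, a regulator of the kidney sodium pump, 727 ± 313 TPM, a log2 fold change of 8.36 ± 0.26 (SE). The tight junction genes Cldn3 and Cldn4 rose by 8.06 ± 0.09 and 7.12 ± 0.08, Krt8 and Krt18 by 7.84 ± 0.16 and 6.78 ± 0.19, and the epithelial cadherin Cdh1 by 4.55 ± 0.18. Of 11 epithelial genes 9 were higher (9 adjusted over the list alone), and the list kept its camera call at an adjusted p = 0.018 with an estimated correlation. Of 10 endothelial genes 7 were higher (7 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), led by Esam at 4.11 ± 0.21. Gzmb stood at 0.358 ± 0.17 TPM (-4.26 ± 0.40) and Gzmc at 0.486 ± 0.192 TPM (-4.10 ± 0.43), and 11 of 12 CD8 T cell and cytotoxicity genes were lower (11 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation). By exact permutation that list did not pass (-1.94, adjusted p = 0.096), nor relative to leukocytes (adjusted p = 0.1; 0.026 with a pseudocount of 0.1). Interferon response genes were lower in 14 of 18 cases (14 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation), with Cxcl10 at -3.93 ± 0.31 and Gbp2 at -3.13 ± 0.36. That list did not pass by exact permutation either (-1.91, adjusted p = 0.1; -1.47 relative to leukocytes, adjusted p = 0.056). MHC class II genes were higher in 7 of 9 cases (7 adjusted over the list alone; adjusted p = 0.88 with an estimated correlation), with the invariant chain Cd74 at 1409 ± 322 TPM. By camera, that list lost its call with median-ratio scaling (limma fit, adjusted p = 0.099) and without replicate 1 of every line (adjusted p = 0.068). By exact permutation its score was higher by 1.57 (adjusted p = 0.035), and by 2.01 relative to the leukocyte score (exact permutation, adjusted p = 0.012). Ccl17, a chemokine of mature dendritic cells, and Lcn2, an iron-binding protein of neutrophils and epithelia, rose to 35.4 ± 14.9 and 86.5 ± 16.7 TPM. Serpinb9d rose by 7.84 ± 0.10, though it belongs to a family of close paralogs that may share reads. Hmga2 (-5.48), Rhox5 (-5.37), Plod2 (-5.16), Ptgs2 (-3.90) and Arg1 (-3.57) were lower. The counts were 2224 genes higher and 1890 lower, at a leukocyte score difference of -0.44. The larger side turned with B16F1 and B16F10 left out (2092 higher, 2440 lower), a pseudocount of 0.1 (3011 and 3439) and no fold threshold (4699 and 6207), and without Renca replicate 3 (2268 and 2269).

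B16F1 and B16F10 libraries held melanocyte genes at high levels, with all 10 members of that list higher in each (10 in each adjusted over the list alone). The camera calls were lost at an adjusted p = 0.29 and 0.12 with an estimated correlation. Dct, an enzyme of melanin synthesis (chromosome 14, 118012790 to 118052244), averaged 2983 ± 1820 TPM in B16F1 (SD, n = 3), a log2 fold change of 9.93 ± 0.23 (SE), and rose by 10.50 ± 0.23 in B16F10. Tyrp1 rose by 5.94 ± 0.16 in B16F1 and 11.02 ± 0.16 in B16F10, Pmel by 7.35 and 9.91, Mlana by 6.95 and 8.56, Trpm1 by 6.17 and 7.87, Slc45a2 by 5.77 and 7.94, and the neural crest factor Sox10 by 7.27 and 6.63. Tyr, the rate-limiting enzyme of melanin synthesis, rose by 7.28 ± 0.25 in B16F10. In B16F1, Gpnmb, a glycoprotein of melanosomes and macrophages, reached 1571 ± 599 TPM, and Ptgds, Col2a1 and Serpina3n rose by 8.54, 8.47 and 7.55. Syt4, a vesicle protein, rose by 8.04 ± 0.19 in B16F10. All 10 MHC class I genes were lower in B16F1 (10 adjusted over the list alone; adjusted p = 0.64 with an estimated correlation). The class I heavy chain H2-D1 stood at 98.0 ± 43.5 TPM, against an average of 1906 TPM over the other lines, and H2-K1 at 109 ± 53.3. Of 13 neutrophil genes 12 were lower in B16F1 (12 adjusted over the list alone; adjusted p = 0.72 with an estimated correlation), with S100a9 at -5.50 ± 0.54 and S100a8 at -4.35 ± 0.44. Interferon response genes were lower in 16 of 18 cases there (16 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation), with Ifi44 at -4.24 ± 0.28. By exact permutation the neutrophil score passed (-2.57, adjusted p = 0.012) and the interferon score did not (adjusted p = 0.06). Relative to leukocytes, whose score was low in B16F1, the differences were -0.94 (adjusted p = 0.16; 0.018 with a pseudocount of 0.1) and -0.47 (adjusted p = 0.64). Ptges fell in both lines (-4.60 and -4.83), as Il1rl1 (-5.82) and Cav1 (-5.67) did in B16F1.

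All 12 fibroblast genes were lower in B16F10 (12 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), with Col3a1 at -6.23 ± 0.32, Dcn at -5.66 ± 0.31 and Col1a2 at -5.50 ± 0.33. Col6a1 (-6.37), S100a6 (-6.17) and Spp1, an osteopontin of macrophages and stroma (-5.35), were lower too. Of 15 hypoxia and glycolysis genes 8 were higher and 3 lower (11 called when adjusted over the list alone; adjusted p = 0.75 with an estimated correlation), with Car9, a carbonic anhydrase induced by low oxygen, at 242 ± 23.3 TPM. By exact permutation the fibroblast score passed (-4.01, adjusted p = 0.0062; -2.19 relative to leukocytes, adjusted p = 0.017). The hypoxia score passed only relative to leukocytes (2.71, exact permutation adjusted p = 0.026, against 0.89 and 0.27). B16F1 had 1528 genes higher and 2366 lower. B16F10 had 948 higher and 4158 lower as deposited, 18.6% higher, and 1832 higher and 2669 lower with median-ratio scaling, 40.7% higher. Leukocyte scores differed from the other lines by -1.63 and -1.82, and mitochondrial transcripts averaged 23.2% and 27.9%.

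Pairs of related lines were compared directly, and MC38OVA against MC38 asks what goes with the added model antigen ovalbumin. Lyz2, the lysozyme of macrophages and neutrophils (chromosome 10, 117277331 to 117282321), averaged 1259 ± 557 TPM in MC38OVA and 294 ± 105 in MC38 (SD, n = 3 each), a log2 fold change of 2.05 ± 0.42 (SE; limma adjusted p = 0.011). The scavenger receptor Cd36, the transferrin gene Trf, Vcan, Thbs1, Tlr9, Ms4a4a, Sirpb1c, Rassf4 and the phagocyte oxidase subunit Cybb rose by 1.65 to 1.95. Ccl9, the macrophage growth factor receptor Csf1r and Apoe rose by 1.56, 1.55 and 1.55. Alas2, the haem synthesis enzyme of red cell precursors, averaged 10.2 ± 3.93 TPM against 131 ± 149 TPM (44.9 without MC38 replicate 3), with Hbb-bt at -2.96 and Hbb-bs at -2.95. Haemoglobin transcripts took 3.86% of TPM in MC38 replicate 3. Small RNA genes Rn7s6, Rpph1, Rnu1b6 and Rnu3b4 fell by 1.46 to 2.98, and Avil, Bpgm and H4c6 lay between -1.25 and -1.48. Of 235 called genes 205 were higher and 30 lower, and camera passed 15 lists higher and 3 lower. Among them 3 of 18 macrophage genes were called higher (11 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), 1 of 9 monocyte genes (7 adjusted over the list alone; adjusted p = 0.28) and 3 of 20 pattern recognition genes (6 adjusted over the list alone; adjusted p = 0.28). Of 9 MHC class II genes 0 were called (7 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). The pan-leukocyte score differed by 1.06, at an exact permutation p = 0.1, the smallest that 3 against 3 allows. The count rested on single libraries and on the leukocyte score: it was 15 without MC38 replicate 2, 23 and 33 without MC38OVA replicates 2 and 3, 608 without MC38OVA replicate 1, 12 with the score as a covariate and 1 in a fit of the 6 libraries alone.

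CT26NYESO1 against CT26 asks the same of the antigen NY-ESO-1. Pnma5 (chromosome X, 73033981 to 73037103) rose from 1.14 ± 0.732 TPM (SD, n = 3; 0.758 without CT26 replicate 2) by a log2 fold change of 4.63 ± 0.37 (SE; limma adjusted p = 9.7e-10), and the methyltransferase Inmt by 2.92 ± 0.47 and Cldn6 by 2.48 ± 0.14. Ccnb1ip1, Rhbdl2, Spint2, Palm3, Lyz1, Fgf11 and Id3 rose by 1.59 to 2.42. Aldh3a1, an aldehyde dehydrogenase (chromosome 11, 61207537 to 61218421), fell from 74.9 to 0.148 ± 0.151 TPM (-6.01 ± 0.21), the platelet and endothelial adhesion molecule Selp from 48.5 ± 9.44 to 0.347 ± 0.0845 TPM (-5.19 ± 0.17) and Krt20 from 124 ± 10.7 to 4.94 ± 1.42 TPM (-4.42 ± 0.16). Plekha6, Thbs2, Mmp3, Slc1a2, Slit3, Oplah and Scara5 fell by 3.26 to 4.25. Of list members, Dcn (-2.36), Cxcl3 (-2.17), Gpnmb (-2.02) and Lcn2 (-1.73) fell, and Lyz1 kept no call without CT26 replicate 1 (1.61). Of 12 dissociation and stress genes 2, Egr1 at -1.52 and Dusp1 at -1.44, were called lower (4 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). Of 11 T cell genes 0 were called (0 adjusted over the list alone), though camera passed the list as higher at an adjusted p = 0.0018, lost at an adjusted p = 0.74 with an estimated correlation and at 0.068 without replicate 1 of every line. In a limma fit of the 6 libraries alone, Inmt and Id3 were not called. The counts were 68 genes higher and 340 lower, and the leukocyte score differed by -0.01 (exact permutation p = 1.0).

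B16F10 against B16F1 compares a subline with its less metastatic relative. Slc24a5, an ion exchanger of melanosomes (chromosome 2, 125068124 to 125088677), rose from 1.31 ± 0.556 to 303 ± 51.5 TPM (SD, n = 3 each), a log2 fold change of 7.06 ± 0.21 (SE; limma adjusted p = 5.6e-20), Tyrp1 by 4.58 ± 0.22 and Tyr by 4.19 ± 0.33. Of 10 melanocyte genes 6 were higher (6 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation). Fbln5, Syt4 and Dkk3 rose by 6.70, 6.62 and 5.53. Red cell genes rose together, with Hbb-bt at 5.99 ± 0.78, Hbb-bs at 5.79, Alas2 at 5.43, Hba-a2 at 5.38 and Hba-a1 at 5.36, and 6 of 8 erythroid and platelet genes were higher and 1 lower (7 called when adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). By camera, that list lost its call with median-ratio scaling (limma fit, adjusted p = 0.08). Haemoglobin transcripts took 4.21 ± 3.21% of TPM in B16F10 and 0.150 ± 0.209% in B16F1, with 7.70% in B16F10 replicate 2 and 0.391% in B16F1 replicate 2. The protease inhibitor Serpina3n fell from 1007 ± 1180 (326 without B16F1 replicate 2) to 0.592 ± 0.265 TPM (-8.60 ± 0.53) and the cartilage collagen Col2a1 from 420 ± 184 to 0.364 ± 0.399 TPM (-8.22 ± 0.19). Mgp, Rhox5, Apod, Serpine2, Prkg2, Col9a1 and Igfn1 fell by 6.15 to 8.04, and Fmod was listed at 0 in B16F10 against 138 ± 148 TPM (54.6 without B16F1 replicate 2). Of 12 fibroblast genes 10 were lower (10 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), including Col5a1 (-3.60), Col3a1 (-3.46), Postn (-3.30) and Col1a1 (-3.05). Spp1 fell by 3.15 ± 0.42. Of 10 MHC class I genes 8 were higher (8 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), with H2-D1 rising from 98.0 ± 43.5 to 491 ± 285 TPM (327 without B16F10 replicate 3). The counts were 813 genes higher and 2937 lower as deposited, 21.7% higher, and 1482 and 2095 with median-ratio scaling, 41.4% higher. The leukocyte score differed by -0.17 (exact permutation p = 0.7).

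**Figure D4:**
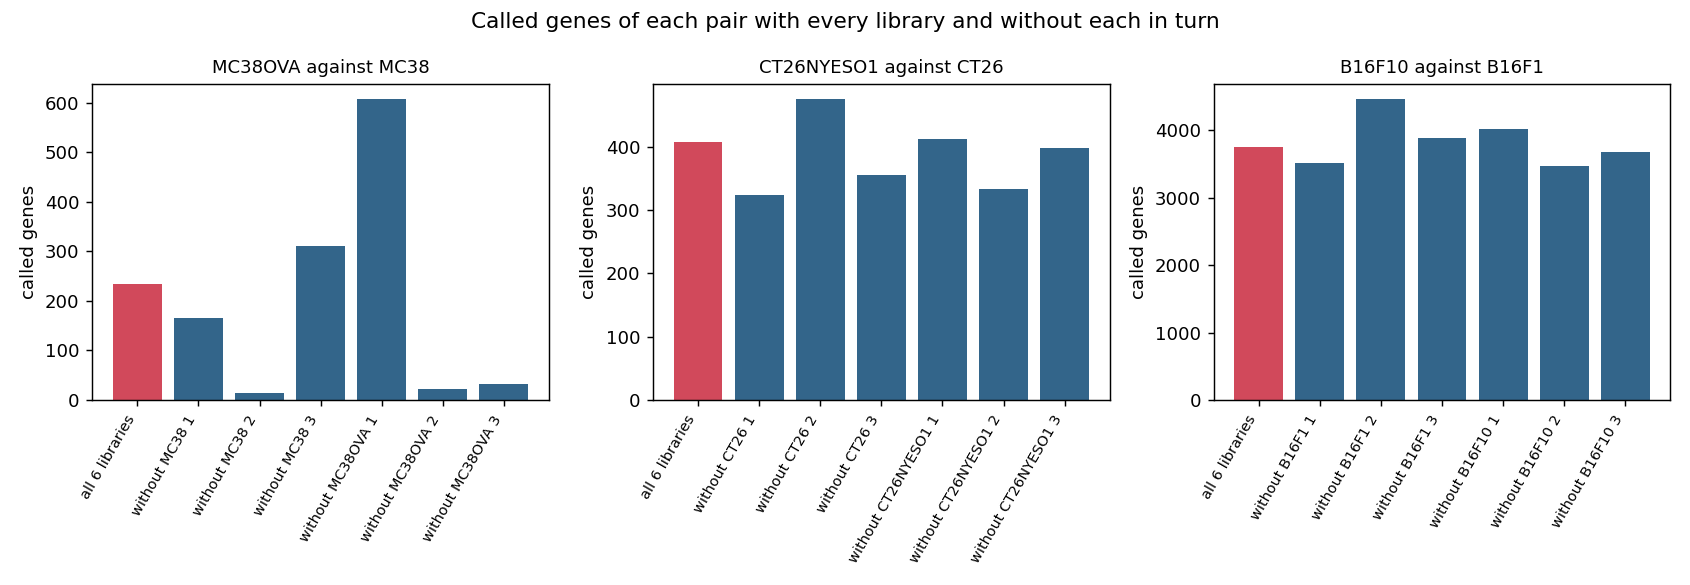
Number of called genes in each of the 3 pairs with all 6 libraries (red bar) and without each library in turn (blue bars), counted in the limma fit over the lines. MC38OVA against MC38 runs from 15 without MC38 replicate 2 to 608 without MC38OVA replicate 1, around 235 with all libraries.

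The antigen pairs were also compared with each other, by the contrast of the MC38OVA change minus the CT26NYESO1 change. Each of the 10 genes named here had its larger change in the CT26 pair. Aldh3a1 changed by -0.11 ± 0.21 (SE) in the MC38 pair and -6.01 ± 0.21 in the CT26 pair, a difference of 5.90 ± 0.29 (limma adjusted p = 1.5e-13, n = 3 per line). Selp, Krt20, Plekha6 and the collagenase Mmp13 differed by 5.62, 4.56, 4.42 and 4.40, and Pnma5, Inmt, Ccnb1ip1, Cldn6 and Rhbdl2 by -5.85, -3.01, -2.65, -2.47 and -2.31. Mmp13 moved in opposite directions, by 1.19 ± 0.29 and -3.21 ± 0.29. Of 470 genes 399 had a larger change in the MC38 pair and 71 in the CT26 pair, in the signed sense. The monocyte list differed in 2 of 9 genes (7 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation). Genes called higher in both pairs numbered 1, against 0.777 for independent lists, and genes called lower 5, against 0.568. Across genes, which are not independent replicates, the changes of the pairs correlated at r = -0.002. The count was 775, 297 and 308 without MC38OVA replicates 1, 2 and 3, and 294 without CT26NYESO1 replicate 2.

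Scores of 6 immune lists were correlated over the 10 line means, 15 relations in all, to ask which compartments rise and fall together. Macrophages went with conventional dendritic cells at Pearson r = 0.79 (permutation p = 0.00784) and Spearman rho = 0.61 (permutation p = 0.066). Neutrophils went with regulatory T cells at r = 0.79 (permutation p = 0.00668) and rho = 0.76 (permutation p = 0.015), and CD8 T cells with regulatory T cells at r = 0.77 (permutation p = 0.00922) and rho = 0.85 (permutation p = 0.00304). All 3 had an adjusted p of 0.0461, and without the 2 lines farthest from the median r was 0.54, 0.82 and 0.70. By rank the adjusted permutation p was 0.165, 0.092 and 0.0456, so only CD8 T cells with regulatory T cells passed. With the leukocyte score subtracted from each list, r was 0.71, -0.20 and 0.35, and none of the 3 passed (permutation, adjusted p = 0.105, 0.698 and 0.481). That subtraction puts a shared term into both scores, which can raise r by itself. After it 2 others passed: regulatory T cells with conventional dendritic cells at r = 0.90, and conventional dendritic cells with B cells at r = 0.86 (permutation, adjusted p = 0.0115 for each). The other 12 relations did not pass as scored. Related lines are not independent, and with 7 families of lines 0 of the 15 passed, as with median-ratio scaling or without the 2 farthest lines.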

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

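Tests chosen only after the result was seen are the comparison of leukocyte scores between B16 and other libraries, the requirement that the immune list result hold at both pseudocounts, and each use of the leukocyte score. The changes of the antigen pairs differed by a test of the difference itself: 470 genes had a change in MC38OVA against MC38 unlike that in CT26NYESO1 against CT26 (limma, n = 3 per line). The differences in log2 fold change were 5.90 for Aldh3a1, 5.62 for Selp, 4.56 for Krt20, 4.42 for Plekha6, 4.40 for Mmp13, -5.85 for Pnma5, -3.01 for Inmt, -2.65 for Ccnb1ip1, -2.47 for Cldn6 and -2.31 for Rhbdl2. Among 100 splits of libraries within the pairs, the real 1 included, 1 gave as many genes, and the highest other gave 445. A split could shuffle 1 pair and keep the real grouping of the other, so 445 need not be a chance count. These splits therefore do not decide whether chance could give the count. Without MC38OVA replicate 1 the count was 775, without its replicates 2 and 3 it was 297 and 308, and without CT26NYESO1 replicate 2 it was 294. No explanation was tested.

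Libraries labelled CD45+ held melanocyte genes in the B16 lines at levels such as 3750 TPM of Tyrp1 in B16F10 (n = 3). Leukocytes that carry free or ingested tumour RNA could produce this. The 6 B16 libraries lay at -1.94 (log2) relative to the other 24, with means of 4.16 ± 0.613 and 6.10 ± 0.616 (SD) and a root of the summed variances of 0.869. RNA of tumour cells in the libraries may explain the pattern too: melanocyte and leukocyte scores went in opposite directions over the 6 libraries at r = -0.55, but weakly (rho = -0.60, exact permutation p = 0.25), and the highest B16 leukocyte score of 4.90 lay only just under the lowest other of 5.02. TPM of each library sum to the same total, so abundant tumour RNA lowers leukocyte values wherever it lies, and neither -1.94 nor r = -0.55 separates the accounts. A sort on CD45 should remove such cells, but the purity of the libraries was not tested. Non-leukocyte genes were abundant beyond B16 too, with Krt8 at 926 TPM in Renca and Col3a1 at 2566 TPM in CMS5a. Whether the libraries hold CD45+ cells alone therefore stays open in other lines as well. No biological explanation was tested.

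Immune lists differed between lines, in 26 of 170 combinations of list and line by exact permutation. A differing share of leukocyte RNA in the library could produce such differences. After the leukocyte score was subtracted, 19.2% of the 26 passed again in the same direction, but 26.9% at a pseudocount of 0.1. The first value lies within a bound written before the test, although the score itself was chosen after seeing the data. The data therefore leave open how much of the pattern the share of leukocyte RNA covers. Another 14 passed only after subtraction. The 5 kept were CD8 T cells and cytotoxicity in MC38, monocytes in MC38OVA, neutrophils in EMT6, mast cells in CT26 and eosinophils in Renca. The subtraction takes each list to move as much as the leukocyte score, which was not tested. Passing it therefore cannot exclude the share of leukocyte RNA for them. Monocyte and leukocyte scores were both highest in MC38OVA (6.642 and 7.119). LL2 had a higher leukocyte score (6.649) than EMT6 (6.307) and Renca (5.321). Its neutrophil score (3.617 against 5.204 in EMT6) and eosinophil score (1.371 against 2.906 in Renca, 2 genes) were lower. These values argue against that share alone for neutrophils and eosinophils. Tumour line stays among the open explanations.

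MC38OVA libraries held higher immune genes than MC38 libraries. The share of leukocyte RNA is a candidate explanation: with the leukocyte score as a covariate, 4.7% of the 235 called genes, 11 in number, were still called in the same direction. The median log2 fold change of the 205 higher genes went from 1.25 ± 0.21 to 0.62 ± 0.30 (SD over genes), while the median SE went from 0.29 to 0.26, so the calls ended because the folds shrank. The covariate and the lines overlap, since the score differed by 1.06 between them, and a higher share of leukocytes in ovalbumin-bearing tumours would itself be biology that these libraries do not separate from how the cells were prepared. The antigen stays an untested explanation.

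For the comparisons of lines, 100 splits of the 30 libraries were counted, the real 1 included, and in each 1 of the 100 gave as many genes. Other splits mix libraries of different lines, which widens the spread within groups and lowers the counts. The splits therefore show that libraries of a line resemble each other. They cannot exclude a chance difference between single tumours or preparations. The real count and the highest of the others were 15338 and 2069 for the test over 10 lines, 2207 and 1350 for MC38, 2471 and 786 for MC38OVA, 2674 and 735 for EMT6, 2604 and 176 for LL2, 2361 and 1915 for CT26, 2252 and 619 for CT26NYESO1, 2462 and 448 for CMS5a, 4114 and 1135 for Renca, 3894 and 148 for B16F1, and 5106 and 2838 for B16F10. The pairs allow 10 splits, too few for a share under 0.05: 235 and 14 genes for MC38OVA against MC38, 408 and 7 for CT26NYESO1 against CT26, and 3750 and 942 for B16F10 against B16F1.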

How the results depend on the processing

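The use of the leukocyte score and the exclusion of B16F1 and B16F10 were chosen after seeing the data, the other alternatives before. Counts of called genes rose with a pseudocount of 0.1, to 3962 in MC38, 4192 in MC38OVA, 4722 in EMT6, 4682 in LL2, 4227 in CT26, 4239 in CT26NYESO1, 4233 in CMS5a, 6450 in Renca, 6065 in B16F1, 8173 in B16F10 and 5696 in B16F10 against B16F1, and went to 66 in MC38OVA against MC38. Without a fold threshold they were, for the same lines, 7821, 7473, 8315, 8815, 7650, 7699, 7728, 10906, 10183 and 12510, and 389, 883 and 7154 for MC38OVA against MC38, CT26NYESO1 against CT26 and B16F10 against B16F1, since smaller changes are then called. Without a filter MC38OVA against MC38 gave 141 genes and the lists of lines 143 calls. The cause was not tested for the changes with pseudocount and filter. MC38OVA against MC38 gave 12 genes with the leukocyte score as a covariate and 1 in a fit of its 6 libraries alone. With an estimated correlation 1 list of the lines and 0 of the pairs passed. Correlations between lists gave 0 with 7 families of related lines (fewer groups), 0 with median-ratio scaling and 0 without the 2 farthest lines (fewer lines), against 3. Genes differing by strain of origin fell to 101 with 7 families (fewer groups). Median-ratio scaling moved the higher share from 18.6% to 40.7% in B16F10 (1832 higher, 2669 lower) and from 21.7% to 41.4% in B16F10 against B16F1 (1482 and 2095).

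With B16F1 and B16F10 left out of the compared lines, falls reversed to small positive values: Dct in MC38 (0.0445), CT26NYESO1 (0.0742) and Renca (0.00174), Tyrp1 in MC38 (0.00169), MC38OVA (0.0184), LL2 (0.0207), CT26 (0.0214) and CT26NYESO1 (0.0109), Pmel in MC38 (0.12) and EMT6 (0.045), and Mlana in MC38OVA (0.0706). The construction shows why, since the melanocyte genes are abundant in the lines left out. The NK cell list of MC38OVA against MC38 reversed without replicate 2 of every line (camera on the limma fit, adjusted p = 0.71, against 1.9e-06 without replicate 3), and the cause was not tested.

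Leaving out single libraries gave 2080 to 2607 genes in MC38, 2346 to 2658 in MC38OVA, 2700 to 2712 in EMT6, 2637 to 2694 in LL2, 2199 to 2607 in CT26, 2216 to 2316 in CT26NYESO1, 2418 to 2685 in CMS5a, 3816 to 4537 in Renca, 3734 to 4520 in B16F1, 4817 to 5510 in B16F10, and 15119 to 15661 in the test over lines. The pairs gave 15 (without MC38 replicate 2) to 608 (without MC38OVA replicate 1) for MC38OVA against MC38, with 23 and 33 without MC38OVA replicates 2 and 3, then 324 to 476 for CT26NYESO1 against CT26 and 3472 to 4472 for B16F10 against B16F1. The difference between the antigen pairs gave 294 (without CT26NYESO1 replicate 2) to 775 (without MC38OVA replicate 1), with 297 and 308 without MC38OVA replicates 2 and 3. List calls were counted without the same replicate number of every line, 10 libraries at once, and ran from 90 to 117 for lines, 29 to 38 for pairs and 28 to 29 over all lines. Each such fit keeps 2 libraries of the line, whose spread is pooled with the other lines.

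Replicate number as a block gave 224 genes for MC38OVA against MC38, 412 for CT26NYESO1 against CT26 and 457 for the difference between pairs, with 691 of 696 named genes and lists keeping their side of the threshold. A pairing by replicate number is not shown by the data: libraries of the same number correlated at a mean r of 0.004 after removal of line means (-0.470 to 0.421), and 12 of 30 were closest to their own number. Of the 696 named genes and lists, 651 kept their call under median-ratio scaling, 657 with a pseudocount of 0.1 and 672 without a filter, and the rest lost it without reversing.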

Other observations

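The comparison described here was planned and the splits of families were chosen after the result was seen. The strain of each line is taken from its known origin, not from the labels. Lines of BALB/c origin (EMT6, CT26, CT26NYESO1, CMS5a and Renca) were set against those of C57BL/6 origin (MC38, MC38OVA, LL2, B16F1 and B16F10), 5 against 5 line means in limma, and 247 genes differed, 211 higher and 36 lower in BALB/c lines. H2-Ea, an MHC class II chain whose gene is defective in C57BL/6 mice, averaged 211 TPM in the BALB/c lines, from 97.8 to 444 TPM, and was listed at 0 in every C57BL/6 line. Ifi202b, H2-Q2 and the pseudogenes Rps18-ps6 and Rps2-ps10 were higher by 6.54, 5.96, 6.54 and 5.72 (log2), and Vill, Zic2, Trim12a, Dclk2 and Deptor were lower, at -3.61, -3.50, -3.43, -2.92 and -2.81. Among 100 splits of the lines into 5 and 5, the real 1 included, 1 gave as many genes and the highest other gave 67, but these splits part related lines that the real split keeps together. With related lines averaged into 7 families the count was 101. Of all 35 splits of the families into 4 and 3 the real 1 alone gave as many, with 3 genes in the highest other. A share of 1 in 35 is the smallest these splits allow, and they were chosen after the result was seen, so they do not exclude chance. The count was 171 to 299 with 1 line left out. A difference of strain, in the host cells, the tumour cells or the mapping of reads to a C57BL/6 reference, may lie behind it, and these cannot be told from tumour type with these libraries, since each line has a single origin. Many of the 247 genes are predicted genes or pseudogenes by name. Col1a2, described above as higher in EMT6, CT26, CT26NYESO1 and CMS5a, was also among them, higher by 4.889 in BALB/c lines (limma adjusted p = 0.0029). Rps2 (-1.456) and Tdg (-1.736) were lower, and their pseudogenes Rps2-ps10, Rps2-ps13 and Tdg-ps2 higher (5.719, 4.431 and 3.355). For these genes, reads mapped to pseudogenes would give such opposite changes. Glo1 and Glo1-ps, in contrast, were both higher (1.465 and 2.876).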
